A study of Mus musculus with 12 samples.

How the data were processed

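RNA from whole livers of female C57BL/6 mice aged 8 to 12 weeks was measured on 12 Affymetrix Mouse430A arrays, 3 for each of 4 groups: HDAC6 knockout, HDAC9 knockout, wild type on a high-fat diet (60% of energy from fat) and wild type on chow (25%). Per the labels, 100 ng of RNA per sample was amplified and labelled with biotin. The values are log2 expression per probe set, deposited by the authors after RMA (robust multi-array average) according to the submitters' processing notes, and the software and chip definition behind them were not given in the sources used here. No further normalization was applied. The values ran from 1.925 to 14.248, and the array medians lay close together, between 5.78 and 5.86. No per-sample column was left unused.

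The table held 22626 probe sets, and a public annotation table gave 20380 of them 1 gene symbol, 691 several symbols and 1555 none. Genes were tested on the probe sets with 1 symbol. Where a gene had several, as 4956 genes did, the probe set with the highest mean over the 12 arrays stood for the gene, which left 12393 genes. Probe sets with several symbols or none were tested apart and are described at the end. No array was left out.

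Groups were compared in R 4.3.3 with limma 3.58.1 (linear model over the 12 arrays with 4 group means, moderated t-statistics with a mean-variance trend). The comparisons were each of the HDAC6 knockout, HDAC9 knockout and high-fat groups against chow, the HDAC9 knockout against the HDAC6 knockout, and the high-fat group against each knockout. Every adjusted p of a gene comes from limma with the Benjamini-Hochberg method over the genes of that comparison, tests were two-sided, and the threshold was an adjusted p under 0.05. The moderated statistics had 14.32 degrees of freedom and a median standard error of 0.124. With 3 arrays against 3 an exact rank test cannot give a p under 0.1. A gene's groups were said not to overlap when all 3 arrays of one lay above all 3 of the other, which happens for 10% of genes by chance.

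Gene lists of pathways, liver zones, sex bias and cell types, 44 in all, were tested with camera in limma (preset correlation between genes of 0.01), with Benjamini-Hochberg adjustment over the 44 lists. A second camera test estimated the correlation from the data, and the rotation test fry was run for one direction and for mixed directions. Members were also tested with adjustment over the list alone. The lists, the comparisons, the thresholds, the probe-set rule and the alternatives were chosen before the data were examined, except for the clock score, the removal of 2 arrays together and the single-array removals for the high-fat group against each knockout, which were added later.

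Genes are named in the text by a fixed rule. Named were Hdac6 and Hdac9, the 10 largest rises and 10 largest falls among called genes of each comparison, and the 4 members of smallest p in lists described. Where fewer than 5 genes were called in a direction, genes of smallest p were added up to 5 and are said not to pass. Genes called in more than 1 chow comparison and called neighbours of the deleted genes were also named.

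Alternatives were a variance prior without a trend, a robust prior, a fit of only the 2 groups compared, array weights, quantile normalization, median centring, removal of genes under the 25th or 50th percentile of mean expression (4.39 and 6.39), the mean of all probe sets of a gene, every probe set on its own, removal of probe sets whose suffix marks shared probes, a minimum change of 1.5-fold, an adjusted p under 0.01, replicate number as a block, and each array left out in turn. The clock score of an array was the mean of Dbp, Tef, Hlf, Nr1d1, Nr1d2 and Per3 minus the mean of Arntl, Npas2, Clock, Nfil3 and Cry1, and was added to the model as a covariate. The array-weight estimation did not converge. The relation expected between comparisons that share the chow arrays was simulated with no effect in 100 draws, and computed from the design for the fits with a chow array left out or the clock score added.

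The procedure was tested on simulated data with the group sizes and variances of these arrays and 200 changed genes. Of 50 genes changed 2-fold, between 46 and 50 were recovered per comparison, and of 50 changed 1.5-fold, between 33 and 41, with 7 to 13 false calls. The Benjamini-Hochberg threshold is easier to pass when many genes change. These shares therefore do not carry over to comparisons in which few genes were called. A list shifted by 0.3 was recovered with an estimated correlation (adjusted p up to 9.43e-06), and 0 other lists were called. The simulated genes varied independently of each other. That count therefore does not show how often lists of correlated genes would be called with no effect. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.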

Results

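Whole livers of female C57BL/6 mice aged 8 to 12 weeks were profiled on Affymetrix Mouse430A arrays, which measure transcripts with short oligonucleotide probe sets. The 12 arrays fell into 4 groups of 3: mice lacking histone deacetylase 6 (HDAC6 knockout), mice lacking histone deacetylase 9 (HDAC9 knockout), wild-type mice fed a diet with 60% of its energy from fat, and wild-type mice fed chow with 25% of its energy from fat. Histone deacetylases remove acetyl groups from histones and other proteins. The labels gave a diet for the wild-type mice and none for the knockouts, so a difference between a knockout and a wild-type group may hold a difference of diet. Expression was read for 12393 genes on a log2 scale, and the array medians lay between 5.78 and 5.86. Pairs of arrays correlated across probe sets at r = 0.987 to 0.998. The number of arrays, 3 per group, limited the precision: the median standard error (SE) of a difference between groups was 0.124 on the log2 scale. The labels number the replicates and do not say in words that each came from its own mouse, so p-values measure the spread between these samples. Arrays are named below by group and replicate number. Xist, the RNA of the inactive X chromosome, averaged 11.63 in the HDAC6 knockout group, 11.73 in the HDAC9 knockout group, 11.86 in the high-fat group and 11.58 in the chow group, and the 6 measured Y-linked genes averaged between 2.54 for Eif2s3y and 5.88 for Sry.

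Hdac6 transcript was low in the livers labelled as lacking it. The Hdac6 probe set read 6.28 ± 0.198 (mean ± SD, n = 3) in the HDAC6 knockout group, against 7.91 ± 0.060 in the chow group, 7.98 ± 0.042 in the HDAC9 knockout group and 7.74 ± 0.262 in the high-fat group. Hdac6 fell 3.10-fold against chow (log2 fold change -1.63, SE 0.133, adjusted p = 6.79e-05), with all 3 knockout arrays below all 3 chow arrays. Hdac9 could not be checked in this way, because its probe set read between 4.04 and 4.53 on every one of the 12 arrays. The group means of Hdac9 were 4.204 ± 0.180 in the HDAC9 knockout group and 4.30 ± 0.109 in the chow group, and genes that liver is not known to express had a median of 3.75. The highest of these background genes, Prm1, averaged 6.93. No gene next to Hdac6 or Hdac9 on its chromosome passed the threshold in any chow comparison. Among the Hdac9 neighbours, Ahr, the aryl hydrocarbon receptor, had a log2 fold change of -0.79 (SE 0.183, adjusted p = 0.230) in the HDAC9 knockout group. That Ahr difference passed when adjusted over the list alone (adjusted p = 0.00894).

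**Figure D1:**
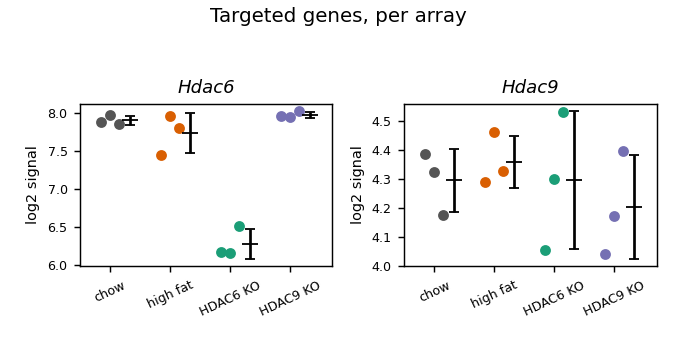
Hdac6 and Hdac9 probe-set values (log2 expression, vertical axis) on each of the 12 arrays by group, with points for arrays and mean ± SD per group. Hdac6 averages 6.28 in the HDAC6 knockout group and at least 7.74 in the other groups, while Hdac9 lies between 4.04 and 4.53 on all arrays.

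The first comparison asked which liver transcripts differed when Hdac6 was deleted, with chow-fed wild-type mice as the reference. Apart from Hdac6 itself, Rab38 was the only gene past the threshold. Rab38, a small GTPase of melanosome transport, rose 1.71-fold (log2 fold change 0.78, SE 0.113, adjusted p = 0.0410), from 5.67 ± 0.074 to 6.45 ± 0.129 (SD, n = 3 each). The next genes by p-value did not pass. Dct, an enzyme of melanin synthesis, had a log2 fold change of 1.06 (SE 0.173, adjusted p = 0.0937), and Olfm3, Sorl1 and Resf1 had values of 0.91, 0.85 and 0.58 (adjusted p from 0.118 to 0.134). On the lower side, Mpp4 had -0.70 (SE 0.117, adjusted p = 0.0937), and Cyp39a1, which hydroxylates oxysterols on the way to bile acids, had -1.002 (SE 0.186, adjusted p = 0.135). The lower group means of Olfm3 (3.91) and Mpp4 (3.47) lay near the background median of 3.75, which limits the sizes given for these genes. Alas1, the first enzyme of heme synthesis, had -0.91 (adjusted p = 0.214), and the organic anion transporter Slc22a7 had -0.61 (adjusted p = 0.302). In all, 1 gene rose and 1 gene fell of the 12393 tested. The knockout and chow arrays did not overlap for 10.1% of genes, where chance gives 10%. The call of Rab38 ended when any 1 of the 6 arrays was left out, with adjusted p up to 0.163 over the settings tried, and after quantile normalization or median centring, which left 0 genes higher and 1 lower. Without HDAC6 knockout replicate 1 the count was 4 genes, and without replicate 2 or replicate 3 it was 1.

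Of the gene lists fixed before the data were examined, 16 were called in the HDAC6 knockout livers with the preset correlation. Other groupings of the same 6 arrays called up to 14 lists. Of the 38 measured cell cycle genes, 33 had lower means than in chow livers (median log2 fold change -0.21, adjusted p = 5.07e-09, and adjusted p = 0.403 with an estimated correlation), with Rrm2 at -0.61 (SE 0.178), Ccna2 at -0.61 (SE 0.180) and Spc25 at -0.85 (SE 0.257). Heat shock and chaperone genes were lower in 24 of 27 (median -0.21, adjusted p = 1.17e-06, and adjusted p = 0.403 with an estimated correlation), among them Hsph1 at -0.67 (SE 0.190) and Hsp90aa1 at -0.59 (SE 0.206). Kupffer cell and macrophage markers were higher in 22 of 26 (median 0.21, adjusted p = 2.42e-08, and adjusted p = 0.403 with an estimated correlation), led by the scavenger receptor Marco at 0.97 (SE 0.225), and genes of MHC class II and antigen presentation were higher in 13 of 15 (median 0.21, adjusted p = 7.64e-05, and adjusted p = 0.403 with an estimated correlation), led by their regulator Ciita at 0.57 (SE 0.123). All 22 measured genes of fatty acid synthesis had higher means (median 0.225, adjusted p = 7.64e-05, and adjusted p = 0.563 with an estimated correlation), with Elovl5 at 0.31 (SE 0.087). That list had medians of -0.048, 0.227 and 0.177 on the knockout arrays and -0.153, 0.227 and -0.381 on the chow arrays. The antigen presentation list had 0.005, 0.059 and 0.348 against -0.237, 0.237 and -0.301. Chow replicate 2 thus did not lie below the knockout arrays in either list. Male-biased liver genes were lower in 19 of 23 (median -0.24, adjusted p = 0.000160, and adjusted p = 0.433 with an estimated correlation), including Hsd3b5 at -2.52 (SE 0.618) and Cyp2d9 at -1.003 (SE 0.247). None of the 16 lists called in this comparison stayed past the threshold with a correlation estimated from the data. No member of these 6 lists passed over all genes. Adjusted over the list alone, 2 Kupffer cell genes (Marco and Mpeg1) and 1 antigen presentation gene (Ciita) were higher and 7 male-biased genes were lower, and no cell cycle, heat shock or fatty acid synthesis gene passed. The call of the male-biased list ended without chow replicate 1 (adjusted p = 0.211).

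The second comparison asked the same of Hdac9. The 2 largest falls in the HDAC9 knockout livers were in Hsd3b5 and Slco1a1, which male mice normally express more than females. Hsd3b5, a steroid-metabolising enzyme, fell 12.3-fold (log2 fold change -3.62, SE 0.618, adjusted p = 0.0463), from 8.11 ± 1.43 in chow livers to 4.485 ± 0.354 (SD, n = 3 each). The knockout value is near background, where genes that liver is not known to express have a median of 3.75, which limits the size given. Slco1a1, an uptake transporter for organic anions and bile acids, fell 11.1-fold (log2 fold change -3.47, SE 0.589, adjusted p = 0.0463), and the glucuronosyltransferase Ugt2b1 fell 1.59-fold (SE 0.104 on the log2 scale, adjusted p = 0.0377). Fmo1, a flavin-containing drug oxidase, fell 5.68-fold (log2 fold change -2.50, SE 0.432, adjusted p = 0.0463), with 10.63, 8.16 and 8.37 on the 3 knockout arrays. Gpx7, the centromere gene Cenpk and Mpp4 also fell past the threshold, but they averaged 4.49, 4.07 and 3.49 in the knockout group, near that background, so the size of their falls is not given. Orm2, an acute phase protein, rose 2.94-fold (log2 fold change 1.55, SE 0.252, adjusted p = 0.0454), lipoprotein lipase (Lpl) rose 2.35-fold (SE 0.208 on the log2 scale, adjusted p = 0.0463) and Rgs1, a regulator of G-protein signalling in leukocytes, rose 2.05-fold (SE 0.133, adjusted p = 0.0202). The chow mean of Rgs1, 4.73, lay near background, which limits the size given. The cytokine gene Il1b rose by 0.84 (SE 0.127) and the dehydrogenase gene Dhrs7 by 0.74 (SE 0.115), both with adjusted p = 0.0377.

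In all, 5 genes rose and 7 fell in the HDAC9 knockout livers, with 754 genes at an unadjusted p under 0.05, and 12.6% of genes had arrays that did not overlap, against 10% by chance. The calls lay close to the threshold, and their number moved with single arrays more than the fold changes did: over the settings and arrays tried Rgs1 ran from 0.915 to 1.097, Il1b from 0.786 to 0.947 and Ugt2b1 from -0.724 to -0.617, with wider ranges for Fmo1 (-3.294 to -2.057), Hsd3b5 (-4.36 to -2.93) and Slco1a1 (-4.015 to -2.793). The single arrays that moved a value most were HDAC9 knockout replicate 1, without which Fmo1 had -3.294 and Slco1a1 -2.793, and chow replicates 3 and 1, without which Hsd3b5 had -4.36 and -2.93. The count was 0 without HDAC9 knockout replicate 2, HDAC9 knockout replicate 3 or chow replicate 1 (limma, with 729, 598 and 874 genes at an unadjusted p under 0.05), 2 without chow replicate 2 and 7 without chow replicate 3. After quantile normalization 4 genes were higher and 1 was lower. HDAC9 knockout replicate 2 also carried transcripts of the exocrine pancreas, whose list median lay 3.58 above the mean of the 12 arrays there and at 0.10 and -0.39 on the other HDAC9 knockout arrays. Chow replicate 1 held the highest male-biased list median of the 12 arrays, at 0.51, against 0.10 and -0.02 on the other chow arrays, and Hsd3b5 read 9.49, 8.20 and 6.63 on the 3 chow arrays. Each of the 12 calls ended on leaving out at least 4 of the 6 arrays in turn, with adjusted p up to 0.236 for Fmo1, 0.193 for Slco1a1, 0.172 for Hsd3b5 and 0.166 for Orm2.

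**Figure D2:**
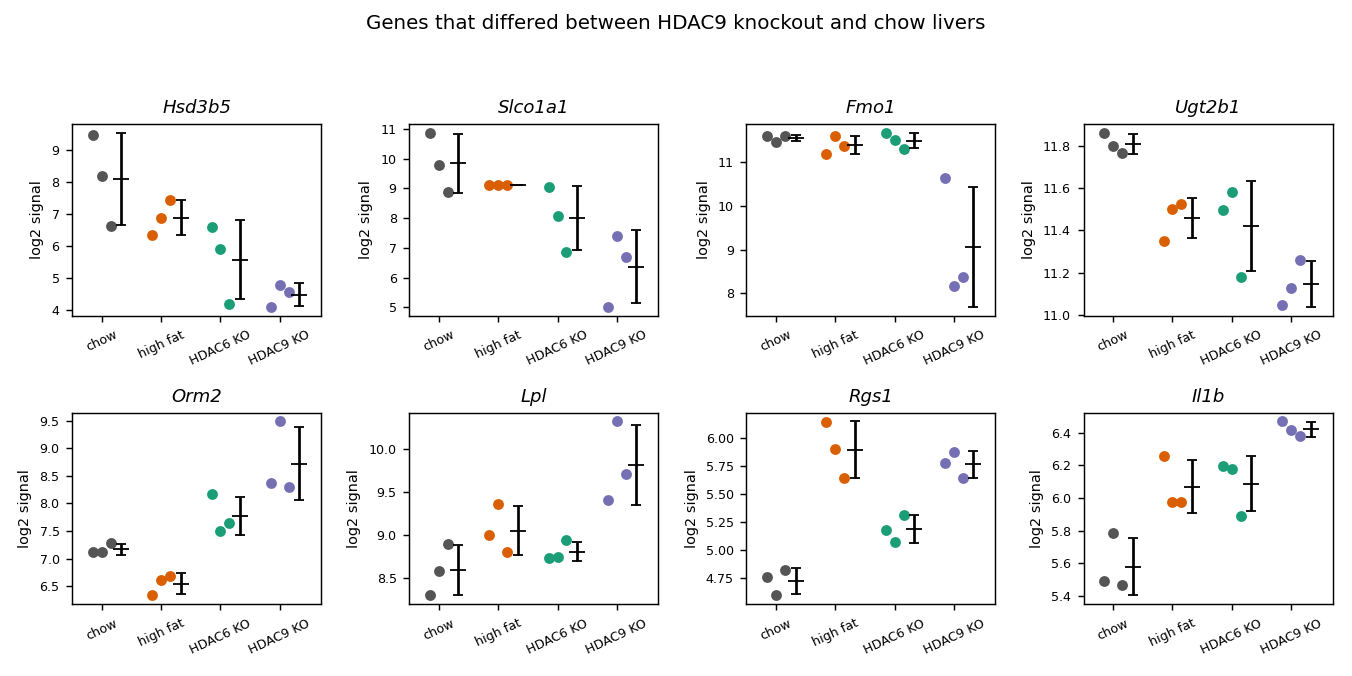
Expression (log2, vertical axis) of Hsd3b5, Slco1a1, Fmo1, Ugt2b1, Orm2, Lpl, Rgs1 and Il1b on each array by group, with points for arrays and mean ± SD per group. In each panel the 3 HDAC9 knockout arrays lie on one side of the 3 chow arrays, and the spread is wide for Hsd3b5 in chow (SD 1.43) and for Fmo1 in the knockout (SD 1.37).

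Several lists were called in the HDAC9 knockout livers with the preset correlation. Other groupings of the same 6 arrays called up to 18 lists, against 16 here. Cell cycle genes were lower in 32 of 38 (median log2 fold change -0.30, adjusted p = 3.66e-13, and adjusted p = 0.183 with an estimated correlation), with Cenpa at -0.74 (SE 0.143) and Spc25 at -1.04 (SE 0.257). None passed over all genes and 12 passed adjusted over the list alone. Male-biased liver genes were lower in 17 of 23 (median -0.205, adjusted p = 5.83e-05, and adjusted p = 0.335 with an estimated correlation), of which Ugt2b1, Slco1a1 and Hsd3b5 fell over all genes and 4 passed adjusted over the list alone, with Hsd3b2 at -1.03 (SE 0.200) the fourth. Pericentral genes, expressed near the central vein of the liver lobule, were lower in 17 of 22 (median -0.19, adjusted p = 1.47e-06, and adjusted p = 0.335 with an estimated correlation), with Cyp1a2 at -0.95 (SE 0.180) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -1.32 (SE 0.303). No pericentral gene passed over all genes and 7 were lower adjusted over the list alone. Bile acid synthesis and transport genes were lower in 24 of 27 (median -0.15, adjusted p = 5.36e-05, and adjusted p = 0.356 with an estimated correlation), where Slco1a1 fell over all genes and 3 passed adjusted over the list alone. The falls of these last 2 lists lay on HDAC9 knockout replicates 2 and 3. The 3 HDAC9 knockout arrays had pericentral list medians of 0.123, -0.316 and -0.284, with 0.009, 0.056 and 0.154 on the chow arrays, and bile acid medians of 0.096, -0.174 and -0.214. The call of the male-biased list ended without chow replicate 1 (adjusted p = 0.144).

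Acute phase genes were higher in 30 of 36 in the HDAC9 knockout livers (median 0.15, adjusted p = 9.49e-08, and adjusted p = 0.360 with an estimated correlation). Without HDAC9 knockout replicate 2 this list was no longer called (adjusted p = 0.0545). Orm2 rose over all genes, and Lrg1 at 0.88 (SE 0.233), Saa1 at 1.56 (SE 0.428) and Lcn2 at 1.69 (SE 0.482) joined it adjusted over the list alone. Kupffer cell markers were higher in 25 of 26 (median 0.24, adjusted p = 1.65e-11, and adjusted p = 0.269 with an estimated correlation), with Cd5l at 0.58 (SE 0.133) the single member past the threshold adjusted over the list alone. Neutrophil markers were higher in 16 of 17 (median 0.20, adjusted p = 1.65e-06, and adjusted p = 0.291 with an estimated correlation), where Il1b rose over all genes and Lcn2 joined it adjusted over the list alone. The neutrophil marker Prtn3 read 8.71 on HDAC9 knockout replicate 2, the array with pancreas transcripts, and at most 4.92 on the other 11 arrays. Without that array the neutrophil list had adjusted p = 0.000203. Lipid droplet genes were higher in 16 of 22 (median 0.14, adjusted p = 0.000415, and adjusted p = 0.183 with an estimated correlation), where Lpl rose over all genes and Cd36, a fatty acid transporter, passed adjusted over the list alone at 1.01 (SE 0.180). Adipocyte markers, a measure of adjacent fat, were also higher in 10 of 12 (median 0.09, adjusted p = 0.00363, and adjusted p = 0.287 with an estimated correlation), with Lpl the single member past the threshold by either adjustment. Adipoq, made by fat cells, read 4.96 on HDAC9 knockout replicate 2 and at most 3.05 on the other arrays, and Lpl was highest there too (10.33, against 9.41 and 9.71 on the other HDAC9 knockout arrays). Without that array the lipid droplet list had adjusted p = 1.60e-05 and the adipocyte list 0.0223. All 17 exocrine pancreas genes had higher means (median 1.38, adjusted p = 4.63e-12, and adjusted p = 0.335 with an estimated correlation), and none passed on its own over all genes or adjusted over the list alone. Without HDAC9 knockout replicate 2 the pancreas list had adjusted p = 7.63e-05 with the preset correlation. The pancreas list medians were 0.104, 3.577 and -0.391 on HDAC9 knockout replicates 1, 2 and 3, and -0.335, -0.307 and -0.391 on the chow arrays. Most of the rise thus lay on replicate 2, and what remained without it lay on replicate 1. No list of the 16 called stayed past the threshold with an estimated correlation.

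The third comparison asked what the high-fat diet did in wild-type livers. Jun, Dusp1 and Zfp36 rose, and Cyp2b10, Csad and Dnase2a had the largest falls. The transcription factor gene Jun rose 6.00-fold (log2 fold change 2.59, SE 0.201, adjusted p = 1.78e-05), from 5.97 ± 0.234 to 8.55 ± 0.167 (SD, n = 3 each). Dusp1, a phosphatase acting on MAP kinases, rose 3.89-fold (SE 0.226, adjusted p = 0.00137), and Zfp36, a protein that promotes decay of messenger RNA, rose 2.81-fold (SE 0.211, adjusted p = 0.00578). Cyp2b10, a drug-metabolising cytochrome P450 induced through the receptor CAR, fell 12.8-fold (log2 fold change -3.68, SE 0.223, adjusted p = 1.27e-06), from 9.01 ± 0.082 to 5.34 ± 0.342. Csad, which makes hypotaurine on the path to taurine, fell 4.25-fold (SE 0.319, adjusted p = 0.0110), and the lysosomal nuclease Dnase2a fell 4.07-fold (SE 0.240, adjusted p = 0.00152).

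Further rises in the high-fat livers included Dntt at 1.75 (SE 0.233), the mitochondrial carrier Slc25a25 at 1.70 (SE 0.302), Stap1 at 1.59 (SE 0.225) and the long noncoding RNA Malat1 at 1.504 (SE 0.264), as log2 fold changes. The clock-controlled gene Noct rose by 1.48 (SE 0.285), Gsap by 1.42 (SE 0.180) and the fatty acid desaturase Fads2 by 1.26 (SE 0.239). The chow means of Stap1 (4.04) and Gsap (4.73) lay near background, which limits the sizes given for them. Further falls were smaller, with the epoxide hydrolase Ephx1 at -1.02 (SE 0.199), the carboxylesterases Ces2a at -0.87 (SE 0.147) and Ces1d at -0.67 (SE 0.122), Nucb2 at -0.80 (SE 0.155) and Myc at -0.77 (SE 0.1495). In all 28 genes rose and 8 fell. In each of the 36 genes the high-fat arrays lay on one side of the chow arrays, which selection by a small p favours, so this adds no support. Over all genes the arrays did not overlap for 14.7%, where chance gives 10%. The called genes had 18 other probe sets, which all pointed the same way, 15 of them at an unadjusted p under 0.05 (limma), and several gave smaller changes. Jun had 1.465 with its other probe set, Dntt 0.936 and 1.356, and Malat1 0.58 (limma, unadjusted p = 0.114) to 1.275. The Cyp2b10, Malat1, Dntt and Dnase2a probe sets used here carry suffixes of probes that can read related transcripts. A Cyp2b10 probe set without such a suffix gave -2.83 (SE 0.247), and Dnase2a had no other probe set. The number of genes past the threshold was 17, 13 and 22 without high-fat replicates 1, 2 and 3, and 23 and 22 without chow replicates 1 and 2. Among the genes named for size of change, Jun, Dusp1, Zfp36, Dntt, Gsap, Cyp2b10 and Dnase2a passed without each of the 6 arrays in turn. The calls of Ephx1, Ces1d, Nucb2, Myc and Malat1 each ended without any of high-fat replicates 1, 2 and 3 or chow replicates 1 and 2, with adjusted p up to 0.223 for Nucb2. The call of Csad ended without high-fat replicate 1, high-fat replicate 2 or chow replicate 2 (adjusted p up to 0.0617), that of Noct without high-fat replicates 2 or 3 or chow replicates 1 or 3 (up to 0.213), that of Fads2 without high-fat replicates 1, 2 or 3 (up to 0.171) and that of Ces2a without high-fat replicates 1 or 2 or chow replicates 1 or 3 (up to 0.120). The call of Slc25a25, whose log2 fold change ran from 1.219 without chow replicate 2 to 2.353 with the clock score in the fit, ended without high-fat replicate 1 or 2 (up to 0.164) and that of Stap1 without high-fat replicate 1 (adjusted p = 0.0505).

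**Figure D3:**
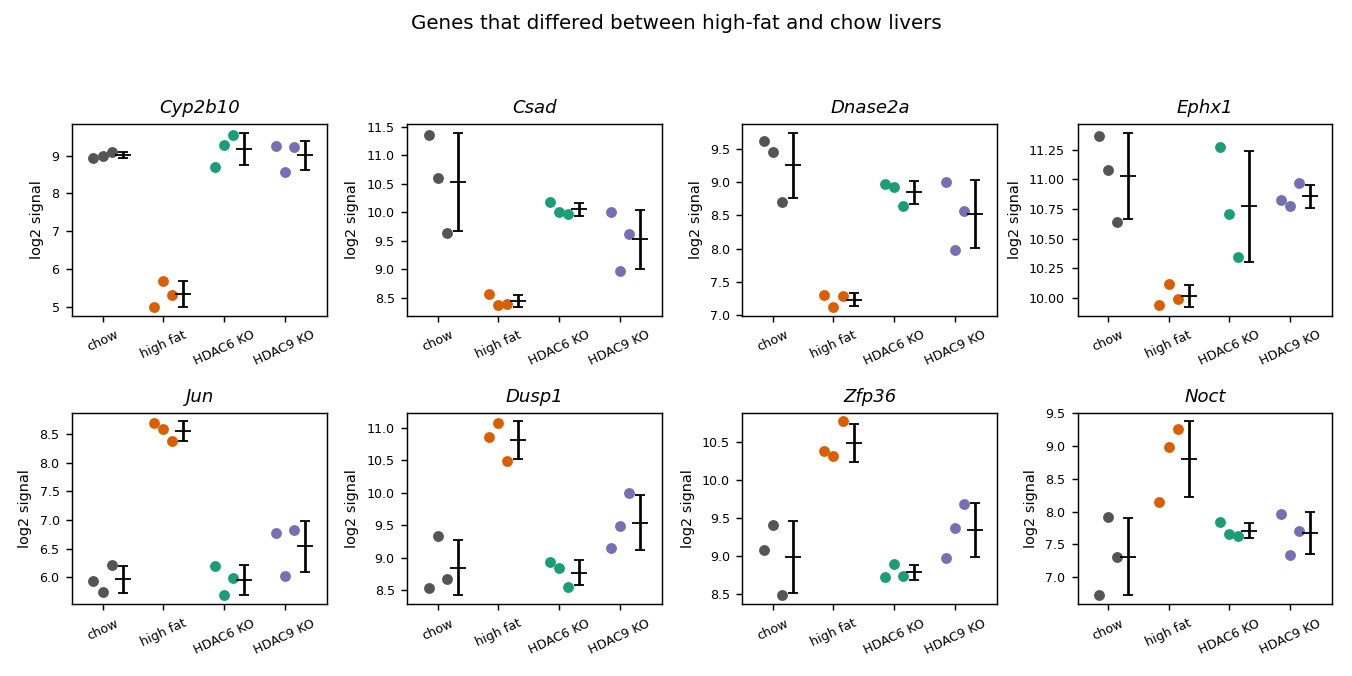
Expression (log2, vertical axis) of Cyp2b10, Csad, Dnase2a, Ephx1, Jun, Dusp1, Zfp36 and Noct on each array by group, with points for arrays and mean ± SD per group. Cyp2b10 averages 5.34 in the high-fat group and 9.01 in the chow group, and Jun averages 8.55 against 5.97.

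The immediate-early list was higher in 23 of 28 genes in the high-fat livers (median 0.32, adjusted p = 2.08e-11). It was the single list of this comparison that stayed past the threshold with a correlation estimated from the data (adjusted p = 0.00184 with an estimated correlation). Its medians were 0.170, 0.096 and 0.187 on the high-fat arrays and -0.120, -0.171 and -0.219 on the chow arrays. The high-fat arrays were the highest of the 12 and the chow arrays the lowest. Part of the size given against chow thus lay in the chow arrays. Jun, Dusp1, Zfp36 and Sgk1, a kinase induced by glucocorticoids, rose and Myc fell over all genes, and 10 members were higher and 1 was lower adjusted over the list alone. The clock score, the mean of evening-phase minus morning-phase clock genes, read 1.63 to 2.79 on the high-fat arrays and -0.68, 1.44 and -0.07 on the chow arrays. With the clock score in the fit 6 genes passed in place of 36, among them Jun, Dusp1 and Cyp2b10. The standard errors grew. The fold changes of the 36 had a median ratio of 0.993 to those without the score, though single genes moved. The circadian list itself did not pass (median 0.38, adjusted p = 0.0508). Noct rose over all genes, and 6 clock genes were higher and 2 lower adjusted over the list alone, with Nfil3 at -1.20 (SE 0.246) and Nr1d1 at 0.89 (SE 0.250). The glucocorticoid list was higher in 12 of 19 (median 0.17, adjusted p = 0.0316, and adjusted p = 0.450 with an estimated correlation), where Dusp1 and Sgk1 rose over all genes and 6 members were higher and 3 lower adjusted over the list alone. Its call ended without high-fat replicate 3 (adjusted p = 0.0759) or chow replicate 2 (0.417).

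Drug metabolism genes under CAR and PXR were lower in 22 of 33 in the high-fat livers (median -0.245, adjusted p = 1.75e-05, and adjusted p = 0.424 with an estimated correlation). Cyp2b10 and Ces2a fell and Cyp2c38 rose (0.90, SE 0.146, adjusted p = 0.0158) over all genes, and adjusted over the list alone 11 were lower and 1 was higher. Interferon response genes were higher in 39 of 41 (median 0.21, adjusted p = 1.35e-11, and adjusted p = 0.424 with an estimated correlation), where the GTPase Gbp3 rose over all genes by 0.86 (SE 0.163), and 7 passed adjusted over the list alone, including Psmb9 at 0.65 (SE 0.129). Kupffer cell markers were higher in 23 of 26 (median 0.24, adjusted p = 3.45e-10, and adjusted p = 0.424 with an estimated correlation), with Marco at 1.04 (SE 0.225) and Cd68 at 0.60 (SE 0.131) among 5 that passed adjusted over the list alone and none over all genes. T and NK cell markers were higher in 27 of 31 (median 0.10, adjusted p = 0.000330, and adjusted p = 0.489 with an estimated correlation) and B and plasma cell markers in 14 of 15 (median 0.12, adjusted p = 0.00525, and adjusted p = 0.483 with an estimated correlation), with no member past the threshold by either adjustment. In the lipid droplet list (median 0.045, adjusted p = 0.0346, and adjusted p = 0.450 with an estimated correlation) the lipid carriers Apoa4 at 0.98 (SE 0.1499) and Fabp2 at 0.98 (SE 0.178) rose over all genes and were also the 2 that passed adjusted over the list alone. Adipocyte markers were higher in 11 of 12 (median 0.085, adjusted p = 0.0316, and adjusted p = 0.450 with an estimated correlation), with no member past the threshold by either adjustment. Female-biased liver genes were higher in 13 of 18 (median 0.29, adjusted p = 0.00272, and adjusted p = 0.483 with an estimated correlation), where Cyp2c38 and Ntrk2 rose over all genes, and 2 were higher and 1 lower adjusted over the list alone. Another Ntrk2 probe set gave 0.08, against 1.09 (SE 0.181) for the one used. The call of Gbp3 ended on leaving out any array but chow replicate 3 (adjusted p up to 0.213) and that of Fabp2 any but high-fat replicate 3 (up to 0.117). Apoa4 was not called without high-fat replicate 2 or chow replicate 2 (up to 0.0704), nor Cyp2c38 without either of these or high-fat replicate 1 (up to 0.103), nor Ntrk2 without high-fat replicates 2 or 3 or chow replicates 1 or 3 (up to 0.114). List calls ended for adipocytes without high-fat replicates 2 or 3 (adjusted p = 0.0780 and 0.0759) or chow replicates 1 or 2 (0.0941 and 0.108), for B and plasma cells without high-fat replicate 1 (adjusted p = 0.0542) or chow replicate 3 (0.0910), for lipid droplets without high-fat replicate 2 (0.302), chow replicate 1 (0.165) or chow replicate 2 (0.197), and for female-biased genes without high-fat replicate 2 (0.103) or chow replicate 1 (0.165).

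**Figure D4:**
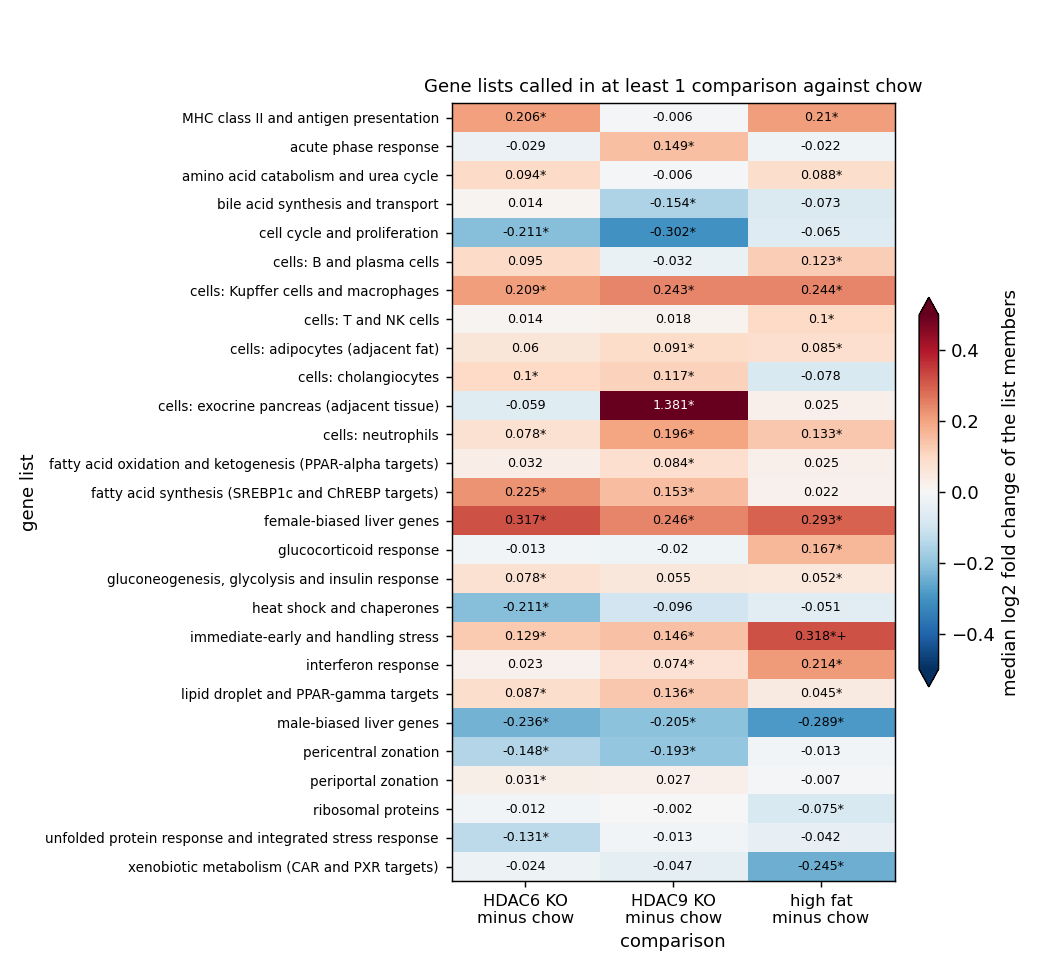
Median log2 fold change (colour scale) of each gene list called in at least 1 comparison with chow, for the 3 chow comparisons, with * where the list was called with the preset correlation and + where it was also called with an estimated correlation. The immediate-early list in the high-fat comparison, with a median of 0.32, is the one entry carrying both marks.

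The knockouts were also compared with each other. Hdac6 was the single gene past the threshold, 3.25-fold higher in the HDAC9 knockout livers (log2 fold change 1.70, SE 0.133, adjusted p = 3.97e-05). The next genes did not pass: Lpl had 1.01 (SE 0.208, adjusted p = 0.578), Syne4 had 0.65, Rgs1 0.58 and Dhrs7 0.52, the neurotrophin receptor gene Ntrk2 had -1.06 (SE 0.181, adjusted p = 0.230), Fmo1 had -2.44 (SE 0.432, adjusted p = 0.230), Arhgap5 -0.63, Ap4s1 -0.53 and Cenpk, near background in the HDAC9 knockout, -0.61. Of 44 lists, 10 were called. The exocrine pancreas list was higher in the HDAC9 knockout livers (median 1.44, adjusted p = 1.88e-14), also without HDAC9 knockout replicate 2 (adjusted p = 7.49e-09). Most of its size lay on that array. Its medians were 0.104, 3.577 and -0.391 on HDAC9 knockout replicates 1, 2 and 3, and -0.618, -0.466 and -0.262 on the HDAC6 knockout arrays. Acute phase genes were higher in 33 of 36 in the HDAC9 knockout livers (median 0.22, adjusted p = 6.15e-11), heat shock genes in 22 of 27 (median 0.10, adjusted p = 0.000533), and bile acid genes were lower in 22 of 27 (median -0.17, adjusted p = 0.000227). No member passed over all genes or adjusted over the list alone in these 4 lists, and all 4 had adjusted p = 0.568 with an estimated correlation. The acute phase medians were 0.08, 0.436 and -0.005 on HDAC9 knockout replicates 1, 2 and 3, and -0.011, -0.139 and 0.001 on the HDAC6 knockout arrays. The highest thus lay on replicate 2, the array with pancreas transcripts, and replicate 3 did not lie above all HDAC6 knockout arrays. Without HDAC9 knockout replicate 1 the count of genes was 4, and without HDAC9 knockout replicate 3 the count of lists was 18. The heat shock list was not called without HDAC6 knockout replicate 3 (adjusted p = 0.482).

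Whether the effect of diet differed from the effect of each deletion was tested by setting the high-fat group against each knockout group. Against the HDAC6 knockout livers 11 genes were higher in the high-fat livers and 7 lower. With replicate number as a block 11 were higher and 15 lower, and without HDAC6 knockout replicate 3 the counts were 12 and 12. Jun was 6.04-fold higher (SE 0.201, adjusted p = 1.70e-05), Dusp1 4.09-fold (SE 0.226, adjusted p = 0.000699), Zfp36 3.24-fold (SE 0.211, adjusted p = 0.00230) and Slc22a7 2.50-fold (SE 0.134, adjusted p = 0.000289). Hdac6, Fabp2, Gnpda1 and Bco1 were higher by log2 fold changes of 0.68 to 1.47. Stap1 was higher by 1.31, a size limited by the knockout mean near background at 4.32. Adgrf1 also passed, but at 3.31 against 2.64 both groups lay under the background median of 3.75. Cyp2b10 was 14.26-fold lower (SE 0.223, adjusted p = 7.14e-07), Dnase2a 3.07-fold lower (SE 0.240, adjusted p = 0.00928) and Cd36 2.23-fold lower (SE 0.180, adjusted p = 0.0150). Ces2a, Mme and Rab38 had log2 fold changes of -0.77 to -1.07. Col4a5 had -0.875, a size limited by the high-fat mean near background at 4.43. The immediate-early list was higher (median 0.14, adjusted p = 8.83e-05, and adjusted p = 0.0409 with an estimated correlation), with 3 members higher over all genes and 6 higher and 1 lower adjusted over the list alone. The gene count was 8 without HDAC6 knockout replicate 2. Jun, Dusp1, Zfp36, Slc22a7, Hdac6, Cyp2b10 and Ces2a passed without each of the 6 arrays in turn. The calls of the other genes ended without HDAC6 knockout replicate 2, apart from that of Rab38, which ended without high-fat replicate 2 (adjusted p = 0.0631). Over the arrays left out their adjusted p ran up to 0.225 for Col4a5 and 0.204 for Stap1.

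Against the HDAC9 knockout livers 33 genes were higher in the high-fat livers and 21 lower. Fmo1 was 5.06-fold higher (SE 0.432, adjusted p = 0.0316), with a wide spread in the knockout (9.05 ± 1.37, against 11.39 ± 0.2, SD, n = 3 each). Jun was 4.04-fold higher (SE 0.201, adjusted p = 0.000457), the retinol dehydrogenase gene Rdh9 3.37-fold (SE 0.282, adjusted p = 0.0157) and Slc22a7 2.22-fold (SE 0.134, adjusted p = 0.00160). Dusp1, Lhpp, Ntrk2, Lect2 and Zfp36 were higher by log2 fold changes of 1.14 to 1.26. Stap1 was higher by 1.55, a size limited by the knockout mean near background at 4.08. Cyp2b10 was 12.7-fold lower (SE 0.223, adjusted p = 1.30e-06), Orm2 4.52-fold lower (SE 0.252, adjusted p = 0.00160), Cd36 2.78-fold lower (SE 0.180, adjusted p = 0.00223) and the clock repressor gene Nfil3 2.69-fold lower (SE 0.246, adjusted p = 0.0243). Slc41a2, Atp11a, Dnase2a, Celsr1, Zfp810 and Cyb561 had log2 fold changes of -1.16 to -2.14. Of 19 other probe sets of the called genes 17 pointed the same way, 12 of them at an unadjusted p under 0.05 (limma). The other Atp11a probe set gave -0.118 (limma, unadjusted p = 0.362), against -1.316, and the other Ntrk2 probe set 0.102, against 1.197. Cell cycle genes were higher in 33 of 38 (median 0.19, adjusted p = 1.80e-09, and adjusted p = 0.408 with an estimated correlation), where Cenpa at 0.79 (SE 0.143) and Ccne2, with both groups under the background median, passed over all genes and 8 passed adjusted over the list alone. With an estimated correlation 0 lists passed in this comparison, so the immediate-early list did not pass either. The gene count moved with single arrays, to 97, 25 and 23 without HDAC9 knockout replicates 1, 2 and 3 and to 10, 25 and 9 without high-fat replicates 1, 2 and 3. Of the genes named here Jun, Slc22a7, Cyp2b10, Orm2 and Cd36 passed without each of the 6 arrays in turn. The calls of the others ended without at least 1 of high-fat replicates 1 and 3, with adjusted p up to 0.119 for Fmo1 and 0.232 for Atp11a over the arrays left out.

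The comparisons with chow share 3 arrays, so their fold changes are related even with no effect. Rgs1 was the only gene called in more than 1 of them: it rose in the HDAC9 knockout livers (1.04, SE 0.133) and in the high-fat livers (1.17, SE 0.133, adjusted p = 0.00137). Its mean was 4.73 in the chow group and 5.185 in the HDAC6 knockout group, so low chow arrays may hold part of both rises. Simulations of no effect with the shared chow arrays gave 0 genes called in both. With no effect in any group few genes can be called at all, so that 0 does not measure how far the shared chow arrays raise the overlap. Independent lists of these sizes would share 0.0113 genes among those that rose, a value that leaves out the shared arrays. Without chow replicate 1 or chow replicate 2 that count was 0. The HDAC6 knockout and high-fat comparisons shared 0 called genes, and 1 without chow replicate 1, 2 or 3 (limma, with 715 and 1051 genes at an unadjusted p under 0.05). Across genes, which are not independent replicates, the HDAC6 and HDAC9 knockout fold changes correlated at r = 0.598, with 0.50 in simulations of no effect, and their covariance was 0.0193 against a simulated 0.0119. The HDAC6 knockout and high-fat changes had r = 0.482 (simulated 0.499) and covariance 0.0165. The HDAC9 knockout and high-fat changes had r = 0.416 (simulated 0.499) and covariance 0.0160, with the same simulated covariance of 0.0119 in each case. Leaving out a chow array raises the correlation that no effect gives to 0.600, and the HDAC6 and HDAC9 knockout changes then correlated at 0.668, 0.603 and 0.697 without chow replicates 1, 2 and 3, so without replicate 2 their excess was 0.003. The other 2 pairs were at or below the value of no effect in each of these fits. The 3 chow arrays cannot be split with 2 in each part, so part of the overlap may come from the shared controls. The same holds for the Kupffer cell list, higher in all 3 comparisons, whose median lay at -0.23, 0.01 and -0.37 on the chow arrays and which had adjusted p = 0.403, 0.269 and 0.424 with an estimated correlation.

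**Figure D5:**
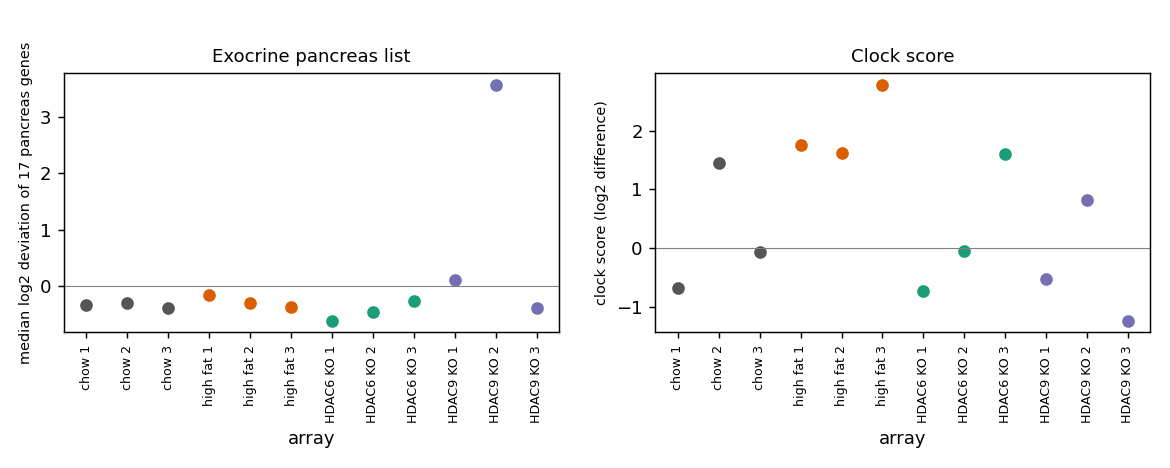
Median deviation of the exocrine pancreas list from the mean of the 12 arrays (log2) and clock score (log2 difference) on each array, by group, with 1 point per array. HDAC9 knockout replicate 2 stands at 3.58 in the pancreas panel, and the high-fat arrays hold the 3 highest clock scores, from 1.63 to 2.79.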

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

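The islet, group expression, handling and time-of-day tests in this part were chosen only after their results were seen. Leaving out single arrays was planned before the data, and the acinar and clock-phase predictions were written before their test values were computed. The acinar prediction also named islet genes, and that part of it was not met. Probe sets with several gene symbols or none, 2246 in all, were tested outside the gene comparisons. In the HDAC9 knockout against chow 1 of them passed the threshold (log2 fold change -0.86, SE 0.114), and in the high-fat group against chow 5 passed, all higher, with values from 1.00 to 1.57. In the high-fat group against the HDAC6 knockout 5 passed and against the HDAC9 knockout 7 passed. Without 1 symbol these probe sets could not be assigned to a gene.

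HDAC9 knockout replicate 2 held transcripts of digestive enzymes of the pancreas. Of 15 acinar genes outside the pancreas list, 11 were highest on that array, where chance gives 1.25. Their lead was often small and near background. The 15 genes had a median excess of 0.42 over the median of the other arrays. Klk1 read 5.87 against at most 3.19 on the other arrays, and Pla2g1b 4.70 against at most 4.68. Of the list itself 15 of 17 were highest there, but that list had singled out the array, so this count adds no support. Cela2a read 9.87 there against a median of 3.89 on the other arrays, though the list was still called without that array (adjusted p = 7.63e-05), with replicate 1 at 0.104. A piece of pancreas taken with that liver may explain the height of that array, while expression in the livers of the group would need the other replicates to share it, and replicate 3 had a list median of -0.391 against a highest chow median of -0.307. The acinar prediction had also named islet genes as highest on that array, and 0 of 9 were. These islet genes lay near background, so they do not decide whether islet tissue was present.

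The immediate-early genes that rose in the high-fat livers were weighed against clock phase, single arrays and handling. With the clock score in the fit, the median ratio of the 5 called differences was 1.034, and Jun went from 2.59 to 2.92. The clock score as it varied within the groups did not account for their size. Every high-fat score lay above every array of the other groups, so the fit cannot exclude a clock difference between the groups. The calls of Zfp36 (adjusted p = 0.0952), Sgk1 and Myc ended with the larger standard error of that fit. No single array carried the list, whose largest adjusted p over the 6 arrays left out was 0.0124 with an estimated correlation. Handling or time to harvest could raise these genes without a diet effect, and the heat shock list, with a median of -0.051 in 27 genes that went both ways, does not decide between them.

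Clock genes of the high-fat livers had the 3 highest scores of the 12 arrays. The lowest high-fat score was 1.626 and the highest of the other 9 arrays was 1.602, in HDAC6 knockout replicate 3. Collection at another time of day could give this pattern, and so could an effect of diet on the clock. The collection times are not given, and these scores cannot tell the explanations apart.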

How the results depend on the processing

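The clock score, the joint removal of HDAC9 knockout replicate 2 and chow replicate 2 and the single-array removals for the high-fat group against the knockouts were chosen only after the results were seen. The genes past the threshold in the HDAC6 knockout against chow (2) became 1 with only the 2 groups in the fit, quantile normalization, median centring, genes above the 50th percentile, every probe set on its own, an adjusted p under 0.01, the clock score, or the 2 arrays left out together, and 831 with array weights, whose estimation did not converge. In the HDAC9 knockout against chow (12) they became 3 without a trend, 6 with a robust prior, 20 with array weights, 5 with quantile normalization or genes above the 25th percentile, 7 with the mean of probe sets and 2 with every probe set on its own. That count was 0 with only the 2 groups, above the 50th percentile, at an adjusted p under 0.01 and with the 2 arrays left out (limma, with 831, 412, 754 and 497 genes at an unadjusted p under 0.05). In the high-fat group against chow (36) the count was 137 with array weights, 22 with the mean of probe sets, 12 at an adjusted p under 0.01 and 6 with the clock score. With that score the median standard error rose from 0.124 to 0.1529. The fold changes of the 36 had a median ratio of 0.993 to those without it, though single genes moved, as Slc25a25 did from 1.70 to 2.353. Between the knockouts (1) it was 682 with array weights and 2 with only the 2 groups, the mean of probe sets or the replicate block. The high-fat group against the HDAC6 knockout (18) gave 34 with the 2 arrays left out, and against the HDAC9 knockout (54) gave 19 with the clock score. With the replicate block, genes called in both were 1 for the HDAC6 and HDAC9 knockouts, 1 for the HDAC6 knockout and high fat, and 2 for the HDAC9 knockout and high fat. Within-group deviations of arrays with the same replicate number correlated at a median of -0.0205 over 18 pairs (-0.152 to 0.148), which gave no sign that the numbers mark pairs. With the clock score the correlations of fold changes were 0.569, 0.397 and 0.145 for the same 3 pairs, where no effect gives 0.482, 0.407 and 0.246. Lists called were 0 (estimated correlation), 0 (fry, directional) and 1 (fry, mixed) in place of 16 for the HDAC6 knockout, 0, 0 and 6 in place of 16 for the HDAC9 knockout, 1, 1 and 14 in place of 16 for high fat (9 of the 14 shared with the preset correlation), and 0, 0 and 1 in place of 10 between the knockouts. Leaving out each array in turn gave 1 to 4 genes for the HDAC6 knockout, 0 to 13 for the HDAC9 knockout, 13 to 33 for high fat, 1 to 4 between the knockouts, 8 to 24 for high fat against the HDAC6 knockout and 9 to 97 against the HDAC9 knockout. Lists between the knockouts numbered 9 to 18. Genes called in both numbered 1 to 1 for the HDAC6 knockout and high fat and 0 to 1 for the HDAC9 knockout and high fat. The correlation of fold changes ran from 0.603 to 0.697 for the HDAC6 and HDAC9 knockouts, from 0.516 to 0.600 for the HDAC6 knockout and high fat and from 0.438 to 0.540 for the HDAC9 knockout and high fat, where no effect gives 0.600 with 2 chow arrays and 0.50 with 3. In the HDAC9 knockout the fatty acid oxidation list turned down without replicate 1 (adjusted p = 0.461, lowest 1.89e-07 without replicate 2) and the interferon list without replicate 3 (adjusted p = 0.821, lowest 5.07e-11 without replicate 1), and neither was called where it turned. The cause of these changes was not tested, apart from the larger standard errors with the clock score.

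Regrouping the 6 arrays of a comparison gives 10 splits, too few for a share under 0.05. The splits with as many genes past the threshold, the real one included, numbered 1 (HDAC6 knockout, real 2, highest other 0), 1 (HDAC9 knockout, 12 and 1), 1 (high fat, 36 and 0), 2 (between knockouts, 1 and 1), 1 (high fat against HDAC6 knockout, 18 and 0) and 1 (high fat against HDAC9 knockout, 54 and 1). For lists called they numbered 1 (real 16, highest other 14), 3 (16 and 18), 3 (16 and 21), 8 (10 and 17), 4 (13 and 18) and 2 (17 and 18) in the same order.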

Other observations

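The values of single arrays in this part were looked up only after the results were seen. Genes of heme, ketone and glucose metabolism were among the smaller changes of the high-fat livers. Hmox1, which degrades heme, rose by 1.12 (SE 0.213, adjusted p = 0.0465), while the NRF2 list to which it belongs had a median of -0.07 (adjusted p = 0.335) and also holds Ephx1, which fell. Bdh1, an enzyme of ketone body metabolism, rose by 0.76 (SE 0.123, adjusted p = 0.0158), with the fatty acid oxidation list at a median of 0.025 (adjusted p = 0.714). G6pc, the last enzyme of glucose release, rose by 0.91 (SE 0.170, adjusted p = 0.0446), in a gluconeogenesis list with a median of 0.05 (adjusted p = 0.0384, and adjusted p = 0.489 with an estimated correlation) that was not called without high-fat replicate 2 or 3 or chow replicate 2 (adjusted p = 0.232, 0.323 and 0.235). The call of Hmox1 ended on leaving out any of the 6 arrays (adjusted p up to 0.199), that of G6pc any but high-fat replicate 3 (up to 0.163) and that of Bdh1 high-fat replicate 1 or 2 or chow replicate 1 or 2 (up to 0.106). Amino acid catabolism genes were higher in 19 of 25 (median 0.09, adjusted p = 0.000205, and adjusted p = 0.483 with an estimated correlation), with Agxt, Tat and Hpd past the threshold adjusted over the list alone and none over all genes.

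Sex-biased genes had list medians in the same direction in each chow comparison. The male-biased list was lower (medians -0.24, -0.205 and -0.29) and the female-biased list higher (0.32, 0.25 and 0.29) in the HDAC6 knockout, HDAC9 knockout and high-fat livers, none past the threshold with an estimated correlation (adjusted p from 0.335 to 0.537). Chow replicate 1 had both the highest male-biased median of the 12 arrays, 0.507, and the lowest female-biased one, -0.395, and that array is a control in all 3 comparisons. Without it the male-biased list had adjusted p = 0.211, 0.144 and 0.535 and the female-biased list 0.167, 0.319 and 0.165 in the same order, so no call remained. The female-biased calls also ended without HDAC9 knockout replicate 1 (0.496) and high-fat replicate 2 (0.103) in their own comparisons. Immediate-early genes were also higher in all 3 chow comparisons, with an adjusted p with an estimated correlation of 0.191 in the HDAC6 knockout and 0.0535 in the HDAC9 knockout livers, against 0.00184 in the high-fat livers. The HDAC6 knockout call ended without chow replicate 3 (adjusted p = 0.0724).

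Other lists did not pass against chow in any of the 3 comparisons. Their smallest adjusted p values were 0.0508 for the circadian and growth hormone lists, 0.0795 for cholesterol synthesis, 0.109 for oxidative phosphorylation, 0.147 for complement and coagulation, 0.153 for erythroid cells, 0.160 for extracellular matrix, 0.216 for stellate cells, 0.374 for endothelium, 0.626 for HDAC6 partners and for histone deacetylases, and 0.694 for hepatocytes.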
